A study of Mus musculus with 28 samples.

How the data were processed

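Per the labels, skin of C57BL/6 mice labelled female was treated with imiquimod cream, an agonist of Toll-like receptor 7 used to provoke psoriasis-like inflammation, or with a control cream for 6 days. Epidermal stem cells were sorted by integrin α6, integrin β1 and Sca1 and by the absence of CD34, and RNA was measured at the end of treatment (day 6), 30 days later (day 30), and 6 h or 12 h after wounds made at day 30. The series holds 28 samples. Of these, 16 RNA-seq libraries in 8 groups of 2 libraries were used; the 12 ATAC-seq samples were not used here.

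Per the labels' protocols, total RNA was taken with Trizol and a Zymo kit and libraries were made with the Illumina TruSeq RNA preparation, which does not mark the strand. Reads were aligned with STAR to mm10 per the submitters' processing notes, in which Bowtie is also named; versions and the gene annotation release are not given in the sources used here. The deposited files hold counts, 1 whole number per gene and library, as the authors made them with STAR's gene counting and without normalization. Each file has 1 count column, and which of STAR's columns it is (unstranded or one of the strands) is not given in the sources used here, so the counts were read as unstranded. The 16 tables hold 47729 gene IDs, of which 47224 matched a symbol in the annotation given with the data (assembly GRCm38, the basis of mm10); 60 symbols were shared by several IDs. IDs without a symbol held 0.0365% to 0.0887% of the counts of a library.

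Library totals ran from 23623968 to 76993427 counts, a ratio of 3.26. Replicates differed by far more than counting error, with a chi-square per gene of 22.9 to 204 within groups, while their log2 CPM (counts scaled to a common library total) correlated across genes at 0.967 to 0.990. Genes are not independent replicates. Statements of precision that rest on counts cover counting error only, since reads were not collapsed to molecules.

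Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM scaling, filterByExpr by group), in 1 fit of the 8 group means over all 16 libraries with 8 residual degrees of freedom. The filter kept 17299 of the 30802 genes with a read. The common biological coefficient of variation was 23.0%. P values are two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05; changes are log2 fold changes with a standard error (SE) from the F statistic, and levels are CPM with the SD of the libraries. A model that shares the spread between genes was needed, since the smallest two-sided exact permutation p for 2 libraries against 2 is 0.333. With a switch from TMM to the median of ratios (RLE) the median of all genes moved by 0.0155 at most upward and by -0.0273 at most downward; with TMM this median was 0.10 at day 6.

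The comparisons were imiquimod against control at each time (day 6, day 30, 6 h and 12 h after wounding), wounding against the unwounded day 30 group within each treatment, the differences between these effects, and the mean of the day 30, 6 h and 12 h effects (the shared comparison). The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for the comparisons of imiquimod, of wounding in control mice and the shared comparison, up to 8 genes per direction with the largest log2 change among genes past the threshold, with a mean of at least 2 log2 CPM and no overlap between the groups. Predicted genes, pseudogenes and receptor segments were left out. It added a panel of 12 genes in every comparison (Krt5, Krt14, Krt10, Krt6a, Krt16, S100a8, S100a9, Il1b, Aim2, Casp1, Stat3 and Mki67) and up to 3 members of each list past its threshold. A gene that this rule names at day 6 is not reported here, though counts of genes include it.

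There were 21 pathway lists and 15 lists of other cell types or of RNA quality, 757 genes in all, of which 753 were found (4 of them under another symbol) and 4 were not. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a kind within a comparison, and again with the correlation estimated per list. The adjusted p printed for a list is that of the preset correlation unless an estimated correlation is named. Members past the threshold were counted after adjustment over all genes and over the list alone. Gene sets drawn in one comparison (adjusted p under 0.05 and absolute log2 change of at least 1) were tested with camera in comparisons that share no library with it.

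Libraries carrying the same replicate number at a time point resembled each other: after group means were removed, their log2 CPM correlated across genes at 0.220 to 0.539 within a time point and at -0.285 to 0.115 (median -0.042) between time points. The number was therefore also fitted as a block within each time point (the replicate block, 4 residual degrees of freedom). The block's value is printed where it changes the call of a named gene or pathway list or moves a count by over 1.5 times. In a test on simulated data for imiquimod at day 30 (16564 genes), the fit without the block recovered 25% of 100 genes changed by 1 and 92% of 100 genes changed by 2 on the log2 scale, with 5 unchanged genes called. With the block these were 37%, 90% and 8 genes. Camera with the preset correlation called 1 of 20 unchanged lists (0 with the block), which leaves the preset untested.

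Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, fits of the compared libraries alone, a block over all libraries, the block within time points, and leaving out each library in turn, where a lone library was assumed to vary like the other groups. Thinning all libraries to 1 total and leaving out the day 30 libraries numbered 1 were added after seeing the data, as was the block within time points for the gene lists, the transferred sets and the differences between wound responses. The alternative of another strand could not be run, since the files hold no other column.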

Results

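RNA was sequenced from sorted epidermal stem cells of mouse skin in 8 groups of 2 libraries. The groups were control and imiquimod-treated skin at day 6, both at day 30, and both at 6 h and 12 h after a wound made at day 30. Total counts in libraries 1 and 2 were 49538267 and 29050534 in day 6 control, 47953381 and 33768837 in day 6 imiquimod, 23928506 and 36218864 in day 30 control, and 23623968 and 29453057 in day 30 imiquimod. They were 56925397 and 27655665 in 6 h control wounds, 76993427 and 26810980 in 6 h post-imiquimod wounds, 36935019 and 70452325 in 12 h control wounds, and 40674917 and 70709213 in 12 h post-imiquimod wounds. Mitochondrially encoded transcripts took 7.65% of counts in library 1 of day 6 imiquimod and 3.31% in library 1 of day 6 control, against 2.48% at most in the other 14 libraries. Both day 30 libraries numbered 1 (1 control and 1 imiquimod) held at most 1 read of Xist, the RNA that silences an X chromosome in females, and 6023 and 7830 reads of Y-linked genes, although the samples are labelled female. The other 14 libraries held 11484 to 71172 Xist reads and at most 2 Y-linked reads. The first 2 principal components of 1000 genes held 46.2% and 28.9% of the variance.

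Imiquimod at day 6 was compared with control to describe the inflamed state itself. S100a9 and S100a8, the subunits of the alarmin calprotectin, rose from 1.13 ± 0.153 to 2559 ± 762 CPM and from 0.91 ± 0.139 to 1710 ± 440 CPM (SD, n = 2 libraries per group). Their log2 changes were 11.13 ± 1.59 and 10.85 ± 1.45 (SE), with adjusted p values of 0.000611 and 0.00043 by edgeR. Also higher were Sprr2d of the cornified envelope (10.04 ± 1.01), Lcn2, which withholds iron from bacteria (9.07 ± 0.92), and the cystine transporter gene Slc7a11 (7.77 ± 0.61). Stfa3 (7.66 ± 1.19), the chitinase-like Chil1 (7.30 ± 1.48) and Cdhr1 (6.89 ± 0.67) rose as well. Leaving out 1 library moved the log2 change between 8.11 and 11.33 for Lcn2, 7.17 and 9.51 for Slc7a11, 6.60 and 9.35 for Stfa3, 4.82 and 8.37 for Chil1 and 6.17 and 9.53 for Cdhr1. Lower were the reelin adaptor gene Dab1 (-6.13 ± 0.52), Skint7 (-5.88 ± 0.36), whose family shapes the T cells of the epidermis, and the cadherin gene Cdh4 (-5.78 ± 0.44). The neurotrophin receptor gene Ntrk2 (-5.53 ± 0.40), Limch1 (-5.06 ± 0.35), the acetylcholinesterase gene Ache (-5.02 ± 0.58), the matrix gene Tnxb (-4.78 ± 0.47) and Cyp2w1 (-4.78 ± 0.66, between -6.44 and -3.98 without 1 library) fell as well. Aim2, a sensor of DNA in the cytosol, rose from 2.23 ± 0.0312 to 26.1 ± 9.57 CPM (3.54 ± 0.33, adjusted p = 1.2e-05). Casp1, the protease that matures interleukin-1β, rose from 11.2 ± 1.06 to 47.5 ± 3.29 CPM (2.08 ± 0.28, adjusted p = 0.000144). On mm10 S100a9 is ENSMUSG00000056071.12 (chromosome 3, 90692630 to 90695721) and S100a8 is ENSMUSG00000056054.9 (chromosome 3, 90669071 to 90670034). Aim2 is ENSMUSG00000037860.15 (chromosome 1, 173349547 to 173466040) and Casp1 is ENSMUSG00000025888.5 (chromosome 9, 5298517 to 5307281).

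Keratins of stressed epidermis rose at day 6, Krt16 from 121 ± 146 to 3768 ± 1382 CPM (4.96 ± 0.94) and Krt6a from 119 ± 159 to 4172 ± 824 CPM (5.13 ± 1.40, adjusted p = 0.0171). Leaving out 1 library moved the log2 change of Krt16 between 4.07 and 7.74 and that of Krt6a between 4.18 and 9.33. The basal keratin Krt5 (0.08 ± 0.33, adjusted p = 0.883) and the differentiation keratin Krt10 (-0.16 ± 0.50, adjusted p = 0.83) did not pass the test. The basal keratin Krt14 (1.10 ± 0.38), the cytokine gene Il1b (1.55 ± 0.55), the transcription factor gene Stat3 (0.65 ± 0.18) and the proliferation marker Mki67 (1.01 ± 0.27) rose, with adjusted p values of 0.0363, 0.0423, 0.0145 and 0.0103. Without library 2 of day 6 control the adjusted p was 0.246 for Krt14, 0.254 for Il1b, 0.0607 for Stat3 and 0.105 for Mki67. Leaving out library 1 of that group gave 0.0797 for Stat3. Without library 2 of day 6 imiquimod it was 0.309 for Krt14, 0.146 for Il1b, 0.118 for Stat3, 0.0797 for Mki67 and 0.052 for Krt6a. Leaving out library 1 of it gave 0.0836 for Il1b. With only the 4 compared libraries in the fit, Krt14 (0.144), Krt6a (0.136), Krt16 (0.0741), Il1b (0.0781) and Stat3 (0.0839) did not pass the adjusted test.

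Genes of epidermal stress and of antimicrobial defence rose together at day 6. Counts over the list alone are adjusted over its members only. Of 20 measured stress keratin and envelope genes 16 rose and none fell (16 higher over the list alone, median 4.67, adjusted p = 3.5e-11, and 0.156 with an estimated correlation), among them Serpinb3a (0.0566 ± 0.005 to 130 ± 47.9 CPM). Of 25 genes of the IL-17 and IL-36 response 19 rose and none fell (20 higher over the list alone, median 4.20, adjusted p = 2.7e-09, and 0.0754 with an estimated correlation), such as the cytokine gene Il19 (0.0619 ± 0.0875 to 90.3 ± 9.87 CPM). Of 19 antimicrobial and alarmin genes 13 rose and 1 fell (13 higher and 2 lower over the list alone, median 4.15, adjusted p = 1.4e-05, and 0.0754 with an estimated correlation). Of 20 basal epidermis genes 10 fell, while 2 rose (3 higher and 10 lower over the list alone, median -0.67, adjusted p = 0.0014, and 0.567 with an estimated correlation). The follicle stem cell keratin Krt15 (-4.18 ± 0.46) and the stem cell receptor gene Lgr6 (-2.52 ± 0.33) fell, and Igfbp2, which binds insulin-like growth factors, rose (5.38 ± 0.70). Without library 1 of day 6 imiquimod the adjusted p of the basal list was 0.0956.

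Among 31 type I interferon genes 9 fell and none rose (9 lower over the list alone, median -0.68, adjusted p = 0.000265, and 0.567 with an estimated correlation). Usp18, which damps interferon signalling, stood at -5.56 ± 0.47, Cmpk2 at -3.09 ± 0.69 and the antiviral Mx2 at -2.90 ± 0.70. Among 28 AP-1 and immediate early genes 11 fell and 2 rose (2 higher and 14 lower over the list alone, median -0.98, adjusted p = 0.000484, and 0.567 with an estimated correlation), with Fosb at -2.27 ± 0.32 and Klf2 at -2.52 ± 0.52. Among 19 circadian clock genes 12 fell and none rose (1 higher and 13 lower over the list alone, median -1.49, adjusted p = 4.5e-06, and 0.0754 with an estimated correlation), with Hlf at -4.27 ± 0.60, Npas2 at -3.60 ± 0.38 and Nr1d1 at -2.64 ± 0.44.

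Genes of growth and metabolism also rose at day 6. All 31 oxidative phosphorylation genes rose (31 higher over the list alone, median 1.05, adjusted p = 2.3e-14, and 0.293 with an estimated correlation), Ndufa4 by 2.47 ± 0.14, Cycs by 1.77 ± 0.29 and Uqcrq by 1.63 ± 0.25. Of 38 cell cycle genes 33 rose and none fell (33 higher over the list alone, median 1.09, adjusted p = 1.0e-09, and 0.54 with an estimated correlation), such as Ccne1 (2.59 ± 0.32) and Rrm2 (2.15 ± 0.21). Of 21 glycolysis genes 15 rose and 1 fell (15 higher and 1 lower over the list alone, median 1.66, adjusted p = 9.7e-07, and 0.45 with an estimated correlation), with the lactate transporter gene Slc16a1 at 4.70 ± 0.74 and the hexokinase gene Hk2 at 3.05 ± 0.65. Of 21 hypoxia genes 11 rose and none fell (11 higher over the list alone, median 0.95, adjusted p = 0.00325, and 0.567 with an estimated correlation), Stc2 by 5.27 ± 0.93 and Car12 by 2.06 ± 0.35. Of 24 unfolded protein response genes 12 rose and 1 fell (13 higher and 1 lower over the list alone, median 0.69, adjusted p = 0.00523, and 0.567 with an estimated correlation), Trib3 by 2.98 ± 0.51 and Asns by 1.42 ± 0.16. Of 26 sterol and lipid synthesis genes 17 rose and none fell (18 higher over the list alone, median 0.81, adjusted p = 0.000235, and 0.567 with an estimated correlation), such as Sqle (2.20 ± 0.36).

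The other 8 pathway lists did not pass at day 6. Over all genes, 8 suprabasal differentiation genes were higher and 3 lower of 27 (adjusted p = 0.203). The numbers were 6 and 9 of 27 interferon gamma and antigen presentation genes (0.203, median -0.32 but mean 0.03). Among NF-kB and TNF targets they were 8 and 4 of 20 (0.387), and among IL-1 and inflammasome genes 6 and 4 of 17 (0.37). Higher and lower genes numbered 6 and 6 of 19 in the STAT3 axis (adjusted p = 0.215) and 7 and 3 of 20 among EGFR ligands and growth factors (0.833). They were 10 and 8 of 41 in wound migration and matrix remodelling (0.629) and 6 and 3 of 16 among heat shock genes (0.514). Markers of macrophages and monocytes rose at day 6, 12 of 16 with none lower (13 higher over the list alone, median 2.75, adjusted p = 0.000518, and 0.785 with an estimated correlation). Adgre1 went from 0.6 ± 0.551 to 10.8 ± 2.42 CPM and the complement gene C1qb from 0.737 ± 0.533 to 8.71 ± 0.112 CPM. The other 14 lists of cells and RNA quality did not pass. Their adjusted p was 0.566 for Langerhans and dendritic cells (4 higher and 1 lower of 11) and 0.838 for T cells (1 and 1 of 4). It was 0.719 for neutrophils (1 and 1 of 4), 0.916 for fibroblasts (1 and 1 of 16) and 0.487 for melanocytes (0 and 0 of 8). Adjusted p was 0.394 for endothelial cells, for muscle and fat, for the hair shaft and inner root sheath, for mitochondrially encoded transcripts and for replication-dependent histones. It was 0.566 for the hair follicle bulge and outer root sheath, for red blood cells and for nuclear long noncoding RNAs, and 0.424 for the infundibulum and sebaceous gland.

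In total 6333 of 17299 genes passed at day 6 by edgeR, 3744 higher and 2589 lower. Without library 2 of day 6 control 4200 passed. With only the compared libraries 49.9% of 4747 called genes were higher, against 59.1% in the fit of all libraries, and without library 2 of day 6 imiquimod 2300 were higher and 2353 lower.

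**Figure D1:**
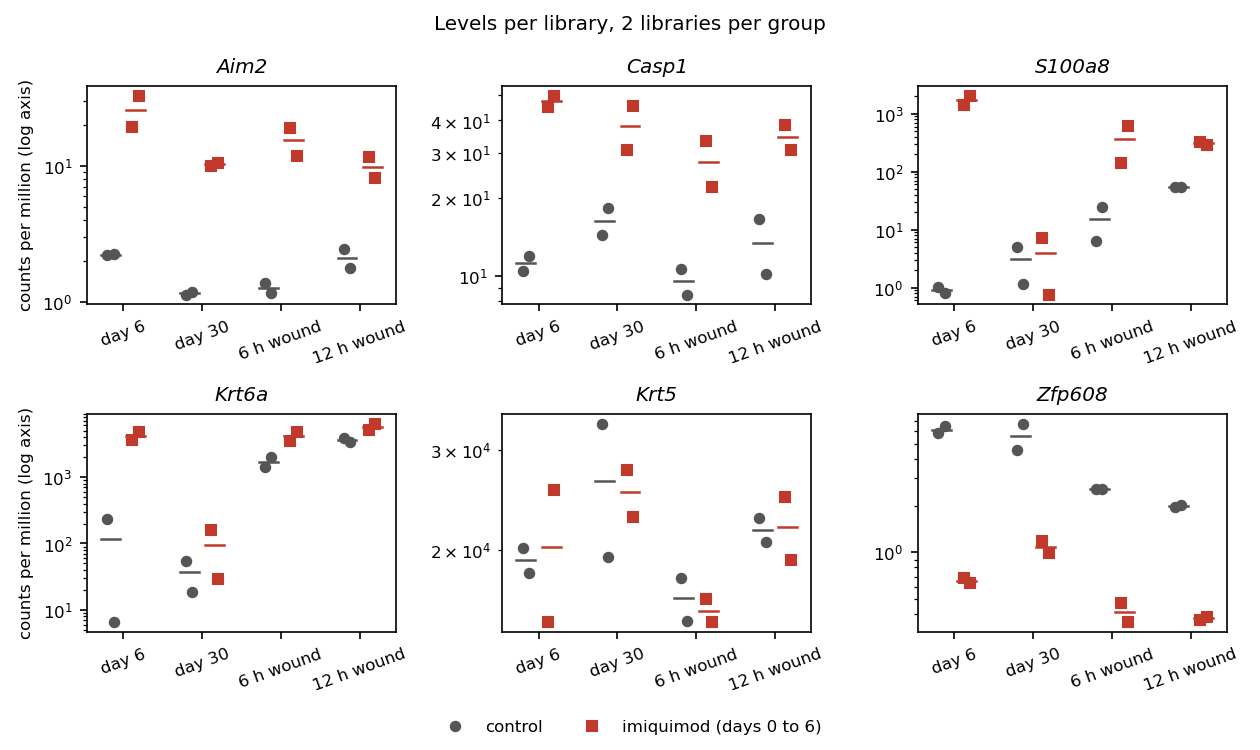
CPM on a log axis for Aim2, Casp1, S100a8, Krt6a, Krt5 and Zfp608 in each of the 16 libraries (points; bars are means of 2 libraries) of control and imiquimod-treated skin at day 6, day 30 and 6 h and 12 h after wounding. At day 30 Aim2 stood at 10.3 CPM after imiquimod against 1.16 in control, while S100a8 stood at 3.91 against 3.11.

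The comparison at day 30 asked what remained of the treatment in unwounded skin. Aim2 was still higher, at 10.3 ± 0.476 against 1.16 ± 0.032 CPM (3.15 ± 0.34, adjusted p = 0.00709, n = 2). Zfp608, a zinc finger gene named after its values were seen, was lower, at 1.09 ± 0.127 against 5.63 ± 1.55 CPM (-2.38 ± 0.31, adjusted p = 0.0266). Casp1 stood at 38.2 ± 10.6 against 16.4 ± 2.74 CPM (1.22 ± 0.28, adjusted p = 0.692), and with the replicate block it passed (1.21, adjusted p = 0.0367). The other panel genes did not pass, with log2 changes of -0.07 for Krt5, -0.27 for Krt14, -0.64 for Krt10, 1.35 for Krt6a, -0.23 for Krt16, 0.36 for S100a8, 0.28 for S100a9, 0.41 for Il1b, -0.07 for Stat3 and -0.01 for Mki67. Of the pathway lists, sterol and lipid synthesis was called lower, although none of its 26 genes passed over all genes (14 lower over the list alone, median -0.58, adjusted p = 6.6e-26, and 0.183 with an estimated correlation). All 26 had a negative change, for example Sqle at -1.04 and Cyp51 at -1.01. The other 20 lists did not pass. In the IL-1 and inflammasome list 1 of 17 genes was higher over all genes (Aim2) and 2 over the list alone (adjusted p = 0.238). The hypoxia list had a median of -0.09 and a mean of 0.01.

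Lists of markers of other cells were called higher after imiquimod at day 30. The median was 1.99 for fibroblasts (adjusted p = 0.0107), 0.57 for Langerhans and dendritic cells (0.0107) and 0.80 for melanocytes (0.0372), with no member past the test over all genes. All 3 had an adjusted p = 0.595 with an estimated correlation. Library 1 of day 30 imiquimod alone had a high fibroblast score (mean log2 CPM of the list), 2.30 against -0.678 in library 2 and -0.390 and -0.086 in control. In all, 2 genes passed at day 30 by edgeR, 716 at an unadjusted p under 0.05, 20 by DESeq2 and 5 with the replicate block. None passed without day 30 control 2, without day 30 imiquimod 2 or with only the compared libraries (0 genes, 298 unadjusted). The block kept Aim2 and added Casp1, the transcription factor gene Runx1 (1.37) and the protease gene Tmprss11g (3.02) as higher and the squalene synthase gene Fdft1 (-0.998) as lower. With the block Zfp608 had an adjusted p of 0.0688, and the suprabasal (down, 0.000814), interferon gamma (up, 0.0189) and IL-1 (up, 0.0153) lists were called, with adjusted p = 0.914, 0.914 and 0.523 with an estimated correlation. Aim2 lost its call without library 1 (adjusted p = 0.0551) or 2 (0.274) of day 30 control or library 2 of day 30 imiquimod (0.0668). With the day 30 libraries of one sex it had a log2 change of 3.17 (adjusted p = 0.216). Zfp608 lost its call without day 30 control 2 (adjusted p = 0.274), day 30 imiquimod 1 (0.206) or 2 (0.278), with thinned libraries (0.0977) and with those of one sex (0.191), where Gpc3, chosen after its values were seen, alone passed (-3.43).

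The effect of imiquimod at day 6 was then tested against that at day 30. It differed for 3894 genes, 2368 more positive and 1526 more negative at day 6 (2528 in all without library 2 of day 6 control). More genes were negative than positive with only the compared libraries (1003 and 769) and without library 2 of day 6 imiquimod (1497 and 1273), of day 30 control (1878 and 1553) or of day 30 imiquimod (1200 and 1029), and the numbers were 1587 and 1586 without library 1 of day 30 imiquimod. Of the 64 genes named at day 6, 48 differed, such as S100a9 (10.85 ± 1.84), Krt16 (5.19 ± 1.19), Krt15 (-4.73 ± 0.60) and Sqle (3.23 ± 0.50). Aim2 (0.40 ± 0.45, adjusted p = 0.575) and Casp1 (0.86 ± 0.38, adjusted p = 0.13) did not differ by this test. Lists more positive at day 6 were stress keratins (12 of 20 genes, 14 adjusted over the list alone, median difference 4.68, adjusted p = 6.5e-12), oxidative phosphorylation (25 of 31, 30 over the list alone, 1.14, 2.6e-14) and sterol and lipid synthesis (18 of 26, 20 over the list alone, 1.38, 3.6e-11), with adjusted p = 0.189, 0.245 and 0.245 with an estimated correlation. So were cell cycle (23 of 38, 31 over the list alone, 1.10, 1.3e-09), glycolysis (13 of 21, 15 over the list alone, 1.70, 6.1e-08), the IL-17 response (10 of 25, 11 over the list alone, 3.76, 4.0e-06) and antimicrobial genes (10 of 19, 10 over the list alone, 4.78, 0.000141). These 4 had adjusted p = 0.484, 0.297, 0.224 and 0.189 with an estimated correlation. Also more positive were the lists of hypoxia (7 of 21, 7 over the list alone, adjusted p = 0.0026), the unfolded protein response (8 of 24, 8 over the list alone, 0.0017) and suprabasal differentiation (7 higher and 2 lower of 27, 0.0297). All 3 had adjusted p = 0.514, 0.508 and 0.669 with an estimated correlation. More negative were circadian clock (8 of 19, 10 over the list alone, 3.4e-05), type I interferon (5 of 31, 5 over the list alone, 0.000194), AP-1 (5 of 28, 7 over the list alone, 0.000343) and basal genes (7 lower and 1 higher of 20, 0.000909). They had adjusted p = 0.189, 0.508, 0.514 and 0.508 with an estimated correlation. Calls ended without 1 library for suprabasal (day 6 control 1, 0.092, day 6 imiquimod 2, 0.0511, day 30 control 2, 0.589, day 30 imiquimod 1, 0.336). They ended too for basal (day 6 imiquimod 1, 0.0579, day 30 control 2, 0.06), hypoxia (day 30 control 1, 0.0521) and unfolded protein genes (day 30 imiquimod 2, 0.0707).

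Wounding was compared with unwounded day 30 skin in control mice to describe the response of cells without earlier inflammation. At 6 h the serine protease inhibitor gene Serpina3n rose from 0.171 ± 0.159 to 228 ± 25.6 CPM (10.56 ± 0.60, adjusted p = 4.6e-06, n = 2) and the chemokine receptor gene Cxcr2 from 0.558 ± 0.08 to 92.1 ± 30.6 CPM (7.38 ± 1.00). Sh2d5 (7.78 ± 1.47), the protein C receptor gene Procr (6.29 ± 1.00), the collagenase gene Mmp13 (6.09 ± 1.33, between 5.10 and 7.86 without 1 library) and the glutathione transferase gene Gsta4 (5.67 ± 1.26) rose too. Depp1 (-4.52 ± 0.61), the semaphorin gene Sema3d (-3.90 ± 0.74), Mlf1 (-3.86 ± 0.42) and the Wnt pathway ligand gene Rspo3 (-3.66 ± 0.68, between -5.26 and -3.01 without 1 library) fell. Stat3 rose from 487 ± 17 to 986 ± 243 CPM (1.02 ± 0.18, adjusted p = 0.00119), while Aim2 (0.14 ± 0.34), Krt5 (-0.69 ± 0.33) and S100a8 (2.35 ± 1.07, adjusted p = 0.12) did not pass. S100a8 (0.0368) and S100a9 (0.0282) had an adjusted p below the threshold with the day 30 libraries of one sex. Krt6a rose from 37 ± 25.6 to 1694 ± 408 CPM (adjusted p = 0.0148, but 0.0867 without day 30 control 2 and 0.0541 without 6 h control 2). Krt10 fell (-2.27 ± 0.53, adjusted p = 0.0058, but 0.0546 without 6 h control 2).

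In control mice 18 of 28 AP-1 genes fell at 6 h of wounding (18 over the list alone). The median was -1.38 (adjusted p = 4.6e-07, and 0.622 with an estimated correlation). Day 6 controls scored 8.13 and 8.01, within the 6 h wounds (7.73 and 8.28), against 9.37 and 9.25 at day 30. Of 26 sterol and lipid synthesis genes 17 fell (20 over the list alone), such as Scd2 (-3.50 ± 0.50). Their median was -1.24 (adjusted p = 6.3e-10, and 0.622 with an estimated correlation). Of 21 hypoxia genes 12 rose (13 higher over the list alone, median 1.02, adjusted p = 0.000108, and 0.622 with an estimated correlation), Car9 by 3.44 ± 0.70. Of 21 glycolysis genes 12 rose and 1 fell (17 higher and 1 lower over the list alone, median 1.12, adjusted p = 0.004, and 0.625 with an estimated correlation), Slc2a3 by 2.08 ± 0.37. Of 17 IL-1 and inflammasome genes 9 fell and 1 rose (2 higher and 11 lower over the list alone, median -0.78, adjusted p = 0.0128, and 0.622 with an estimated correlation), Il18r1 by 2.60 ± 0.34. Suprabasal differentiation was called too (13 of 27 lower, 14 over the list alone, median -1.99, adjusted p = 0.000645). So were stress keratins (7 of 20 higher, 7 over the list alone, median 1.72, adjusted p = 0.0106). Wound migration was called (19 higher and 3 lower of 41, the same over the list alone, median 0.86, adjusted p = 0.00432). So was the IL-17 response (10 higher and 4 lower of 25, 11 and 5 over the list alone, median 1.27, adjusted p = 0.0425). These 4 had adjusted p = 0.625 with an estimated correlation. Both day 30 libraries numbered 2 stood apart in the suprabasal score, at 7.64 in control and 7.13 in imiquimod, against 3.86 to 5.04 in the other 14 (4.75 in day 30 control 1, 4.49 and 4.45 in 6 h control wounds). The suprabasal call ended without day 30 control 2 (adjusted p = 0.277), the stress call without 6 h control 2 (0.0541) and the IL-17 call without day 30 control 1 (0.242). The other 12 pathway lists did not pass, and median and mean differed in sign for basal (0.08 and -0.03) and STAT3 genes (-0.13 and 0.06). No list of other cells passed (0 of 15). In all 6003 genes passed, 3119 higher and 2884 lower (2390 and 2514 without day 30 control 1), against 3252 without 6 h control 2 and 3270 with only the compared libraries.

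At 12 h of wounding in control mice the matrix protease genes Mmp13 (1.14 ± 1.2 to 592 ± 82.3 CPM, 9.17 ± 1.46, adjusted p = 0.00157, n = 2) and Mmp9 (7.36 ± 1.11) rose, between 8.17 and 10.94 and between 6.17 and 10.21 without 1 library. So did Lcn2 (0.405 ± 0.364 to 63.8 ± 0.547 CPM, 7.47 ± 0.91), Cxcr2 (7.77 ± 1.01), the connexin gene Gjb2 (7.41 ± 1.03), the stress keratin Krt6b (8.03 ± 1.68) and the protease inhibitor gene Slpi (6.04 ± 0.65). Lower were the stress-induced factor Atf3 (7538 ± 1775 to 370 ± 68.9 CPM, -4.35 ± 0.55), Btg2 (-4.92 ± 0.46), the orphan nuclear receptor gene Nr4a3 (-5.77 ± 0.98) and Ch25h, which makes 25-hydroxycholesterol (-4.47 ± 0.61). S100a8 rose from 3.11 ± 2.76 to 54.5 ± 0.0116 CPM (4.20 ± 1.12, adjusted p = 0.0196), a call lost without day 30 control 2 (0.0978) or 12 h control 1 (0.06) or 2 (0.0612). Aim2 did not pass (0.86 ± 0.33, adjusted p = 0.0652), and neither did Casp1 (-0.29 ± 0.27) or Krt5 (-0.28 ± 0.33). Of 28 AP-1 genes 23 fell (25 over the list alone, median -2.13, adjusted p = 5.1e-22, and 0.275 with an estimated correlation). Scores (6.70 and 7.01) lay below day 6 controls too. Of 19 circadian clock genes 13 fell (1 higher and 14 lower over the list alone, median -1.85, adjusted p = 6.4e-07, and 0.218 with an estimated correlation), such as Bhlhe40 (-2.73 ± 0.30). Of 20 stress keratin genes 14 rose (15 higher and 1 lower over the list alone, median 3.37, adjusted p = 2.4e-06, and 0.451 with an estimated correlation). Of 41 wound migration genes 20 rose and 3 fell (21 higher and 4 lower over the list alone, median 0.72, adjusted p = 6.9e-07, and 0.451 with an estimated correlation). Of 24 unfolded protein response genes 14 rose and 1 fell (14 higher and 1 lower over the list alone, median 0.77, adjusted p = 0.00155, and 0.565 with an estimated correlation), such as Creld2 (1.79 ± 0.30).

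Among NF-kB and TNF targets 5 fell and 3 rose of 20 at 12 h (4 higher and 7 lower over the list alone, median -0.39, adjusted p = 0.0139, and 0.422 with an estimated correlation), with the feedback inhibitor genes Tnfaip3 at -3.74 ± 0.49 and Nfkbia at -2.48 ± 0.32. Antimicrobial genes (6 higher and 1 lower of 19, 6 higher and 1 lower over the list alone, median 1.51, adjusted p = 0.031, and 0.451 with an estimated correlation) and the IL-17 response (11 and 4 of 25, 12 higher and 4 lower over the list alone, median 1.13, adjusted p = 0.0236, and 0.565 with an estimated correlation) were called higher. Suprabasal differentiation (11 of 27 lower, 15 lower over the list alone, median -1.47, adjusted p = 0.00148, and 0.657 with an estimated correlation) and IL-1 genes (2 higher and 6 lower of 17, 3 higher and 6 lower over the list alone, median -0.62, adjusted p = 0.0344, and 0.451 with an estimated correlation) were called lower. Calls ended for suprabasal genes without day 30 control 2 (adjusted p = 0.393), for the IL-17 response without day 30 control 1 (0.169) and for IL-1 genes without day 30 control 2 (0.113) or 12 h control 2 (0.095). The other 11 pathway lists and the 15 lists of other cells did not pass. In all 5328 genes passed, 2848 higher and 2480 lower (2112 and 2115 without day 30 control 1), against 2924 and 2846 without 12 h control 1 and 2.

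In mice treated with imiquimod before, wounding was compared with day 30 imiquimod. AP-1 genes fell again, 21 of 28 at 6 h and 25 at 12 h (22 and 25 over the list alone). Medians were -1.58 and -2.44 (adjusted p = 3.5e-11 and 1.3e-20, and 0.501 and 0.244 with an estimated correlation). Scores were 7.05 and 7.95 at 6 h and 6.49 and 7.01 at 12 h. Stress keratin genes rose, 15 of 20 at 6 h and 16 at 12 h (17 higher, then 16 higher and 1 lower, over the list alone). Their medians were 3.82 and 4.65 (adjusted p = 5.1e-06 and 2.1e-07, and 0.501 and 0.444 with an estimated correlation). Antimicrobial genes rose (10 of 19 with 1 lower at 6 h, adjusted p = 0.00739, and 9 with 1 lower at 12 h, 0.00185), as did the IL-17 response (13 and 13 of 25, 13 and 14 over the list alone, 0.00125 and 0.00185) and wound migration (20 and 21 of 41, 20 and 24 over the list alone, 0.00216 and 9.3e-06). These 3 had adjusted p = 0.501, 0.501 and 0.669 at 6 h and 0.244, 0.444 and 0.444 at 12 h with an estimated correlation. Clock genes fell (9 and 14 of 19, 9 and 15 over the list alone, 0.00764 and 2.6e-08, and adjusted p = 0.501 and 0.0965 with an estimated correlation). At 12 h sterol synthesis (16 of 26, 18 over the list alone, 3.7e-06), oxidative phosphorylation (14 of 31, 19 over the list alone, 0.000103) and unfolded protein genes (15 of 24, 16 over the list alone, 6.4e-05) rose. They had adjusted p = 0.444, 0.595 and 0.444 with an estimated correlation. Further lists called rested on single libraries. At 6 h suprabasal (down), glycolysis (up), hypoxia (up), oxidative phosphorylation (up), unfolded protein (up) and interferon gamma genes (down) had adjusted p = 0.769, 0.704, 0.675, 0.769, 0.669 and 0.669 with an estimated correlation. Without 1 library their adjusted p reached 0.666, 0.181, 0.109, 0.464, 0.172 and 0.076. At 12 h suprabasal genes (down) had adjusted p = 0.831 with an estimated correlation and up to 0.537 without 1 library. No list of other cells passed (0 of 15 at either time). At 6 h 6695 genes passed (4044 without post-imiquimod 2) and at 12 h 6512 (4202 without post-imiquimod 2). Higher in both treatments were 2473 genes at 6 h (628 if the calls were independent) and 2467 at 12 h (579), and lower in both were 2213 (535) and 2020 (429).

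Prior imiquimod was compared with control in wounded skin to ask whether cells with a history of inflammation differ when challenged again. At 6 h Aim2 was higher, at 15.5 ± 5.05 against 1.27 ± 0.148 CPM (3.60 ± 0.33, adjusted p = 0.00123, n = 2), as was Vav1 (2.28 ± 0.30, adjusted p = 0.0186). The heparan sulfate proteoglycan gene Gpc3 was lower (-2.70 ± 0.37, adjusted p = 0.0219). The remaining 3 calls, chosen after their values were seen, were the oxysterol hydroxylase gene Cyp7b1 (4.58 ± 0.60) and Gm43834 (3.86 ± 0.49) as higher and Zfp608 as lower (-2.58 ± 0.32). S100a8 stood at 372 ± 326 against 15.4 ± 12.7 CPM (4.61 ± 1.09, adjusted p = 0.339). S100a9 stood at 427 ± 393 against 20.4 ± 16.6 CPM and Casp1 at 27.7 ± 8.04 against 9.53 ± 1.5 CPM (1.54 ± 0.28, adjusted p = 0.126). With the replicate block S100a8 (4.55, adjusted p = 0.000138), S100a9 (4.28, 0.000138) and Casp1 (1.53, 0.00492) passed, as did Sprr2d (3.12), the chemokine gene Cxcl1 (1.13) and Lcn2 (1.28). Aim2 lost its call without 6 h control 1 (adjusted p = 0.0606) or 2 (0.0717). Vav1 lost it without either (0.376 and 0.182) or post-imiquimod 2 (0.249). Gpc3 lost it without any of the 4 libraries (at most 0.374, without post-imiquimod 2) and with the block (0.0511).

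At 6 h 19 antimicrobial genes were called higher as a list (6 higher over the list alone, median 1.30, adjusted p = 7.5e-11, and 0.021 with an estimated correlation), though none of them passed over all genes. Higher lists were also stress keratins (5 higher over the list alone, median 1.23, adjusted p = 3.3e-12, and 0.159 with an estimated correlation), the IL-17 response (5 higher over the list alone, median 0.88, adjusted p = 6.0e-10, and 0.159 with an estimated correlation) and IL-1 and inflammasome genes (4 higher over the list alone, median 0.17, adjusted p = 8.2e-05, and 0.159 with an estimated correlation). So were oxidative phosphorylation (1 higher over the list alone, median 0.28, adjusted p = 2.1e-10, and 0.434 with an estimated correlation, 31 of 31 positive) and sterol synthesis (0 over the list alone, median 0.36, adjusted p = 4.6e-06, and 0.47 with an estimated correlation). Clock genes were lower (0 over the list alone, median -0.57, adjusted p = 0.000211, and 0.159 with an estimated correlation). Called with smaller medians, each with adjusted p = 0.516 or more with an estimated correlation, were wound migration (0.15, adjusted p = 0.00307) and the unfolded protein response (0.23, 0.00105) as higher and AP-1 (-0.41, 9.2e-07), type I interferon (-0.33, 0.00424), hypoxia (-0.32, 0.00105), cell cycle (-0.22, 0.00549) and glycolysis genes (-0.17, 0.00176) as lower. Apart from Aim2, no member of the called lists passed over all genes. Without some library the calls ended of IL-1 (adjusted p up to 0.0872), type I interferon (0.781), AP-1 (0.738), glycolysis (0.976) and hypoxia (0.926). So did those of migration (0.0545), the unfolded protein response (0.888) and the cell cycle (0.0538). The last turned higher without control 1 (0.000507). Markers of melanocytes (median -1.22, adjusted p = 0.000113), fibroblasts (-1.80, 8.3e-09), the hair follicle (-0.38, 0.000295) and the hair shaft (-2.23, 0.000206) were lower after imiquimod, with adjusted p = 0.126, 0.28, 0.119 and 0.369 with an estimated correlation. In all 6 genes passed by edgeR at 6 h, 1091 at an unadjusted p under 0.05, 131 by DESeq2, 28 with the block and none with only the compared libraries (1319 unadjusted). Without control 1 or 2 the count was 0 and without post-imiquimod 2 it was 1.

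At 12 h no gene passed by edgeR (0 genes, 425 at an unadjusted p under 0.05, 27 by DESeq2, and 20 with the replicate block, 13 higher and 7 lower). Aim2 stood at 9.93 ± 2.45 against 2.13 ± 0.476 CPM (2.23 ± 0.31, adjusted p = 0.0629, n = 2, 0.00944 with the block) and Casp1 at 34.6 ± 5.4 against 13.4 ± 4.58 CPM (1.37 ± 0.27, 0.00944 with the block). S100a8 stood at 306 ± 27.6 against 54.5 ± 0.0116 CPM (2.49, adjusted p = 0.00869 with the block), and S100a9 passed with the block too (2.27, 0.00869). The block also called Casp4, a sensor of bacterial lipopolysaccharide (1.01), Sprr2d (1.86) and the antigen presentation gene H2-Ab1 (1.45) as higher. It called the clock factor gene Tef (-0.94), Calm5 (-1.38) and Skint7 (-1.15) as lower. Oxidative phosphorylation (0 over the list alone, median 0.27, adjusted p = 3.9e-13, and 0.291 with an estimated correlation, 31 of 31 positive) and interferon gamma and antigen presentation (3 higher over the list alone, median 0.20, adjusted p = 2.8e-07, and 0.189 with an estimated correlation) were called higher as lists. So were the IL-17 response (1 higher over the list alone, median 0.58, adjusted p = 2.2e-06, and 0.189 with an estimated correlation), antimicrobial genes (0 over the list alone, median 0.56, adjusted p = 3.7e-05, and 0.119 with an estimated correlation), stress keratins (0 over the list alone, median 0.46, adjusted p = 8.6e-05, and 0.516 with an estimated correlation) and IL-1 genes (4 higher over the list alone, median -0.02, adjusted p = 0.000616, and 0.189 with an estimated correlation, with a mean of 0.21). Clock genes were lower (0 over the list alone, median -0.37, adjusted p = 2.1e-06, and 0.119 with an estimated correlation). Hypoxia (-0.39, adjusted p = 0.000616), cell cycle (-0.24, 0.000157) and glycolysis genes (-0.16, 0.0147) were called lower and the unfolded protein response higher (0.12, 0.0238). They had adjusted p = 0.725 for hypoxia and 0.8 for the others with an estimated correlation. Calls ended for interferon gamma without post-imiquimod 1 (0.371) and for IL-1 and hypoxia without control 2 (0.0519 and 0.0792). They ended for the unfolded protein response without control 1 (0.416), and for that list, glycolysis and cell cycle without post-imiquimod 2 (0.244, 0.362 and 0.827, the last with the sign turned). Markers of Langerhans and dendritic cells were higher (0.55, adjusted p = 0.000628) and of the hair shaft lower (-1.44, 0.00439), both with adjusted p = 0.74 with an estimated correlation.

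**Figure D2:**
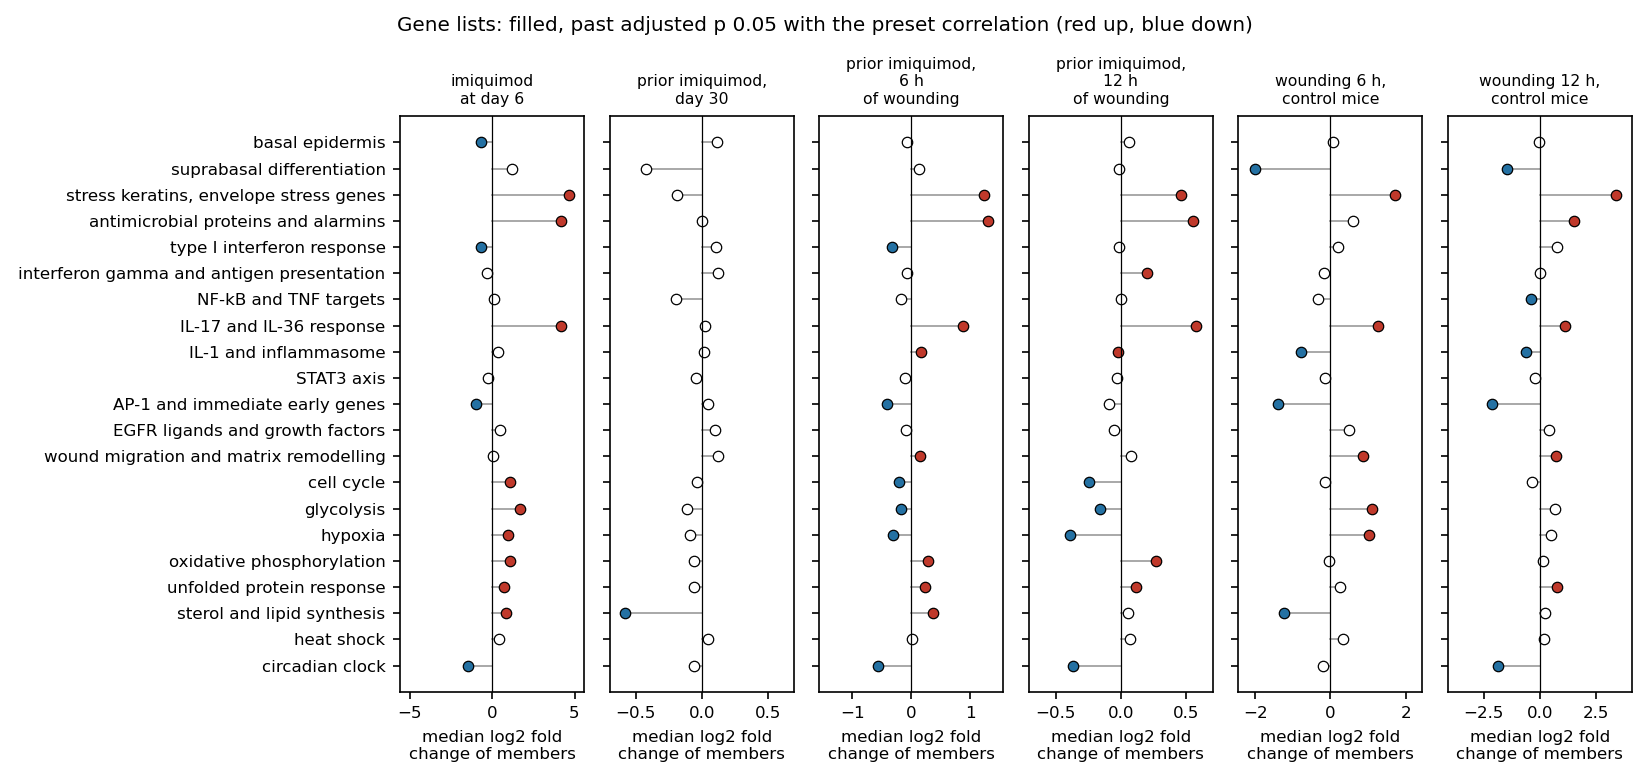
Median log2 fold change of the 21 pathway lists (rows) in 6 comparisons (panels, each with its own scale); filled points passed the preset camera test (red higher, blue lower) and open points did not. Stress keratin genes had medians of 4.67 at day 6, 1.23 at 6 h and 0.46 at 12 h.

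Whether the wound response itself differed after imiquimod was tested as the difference between both wounding effects. No gene passed by edgeR at 6 h (0 genes, 1057 at an unadjusted p under 0.05, 27 by DESeq2). With the replicate block S100a8 (4.42), S100a9 (4.19) and the glycerol kinase gene Gk (1.42) rose more after imiquimod. Sterol and lipid synthesis genes were shifted up at 6 h (15 higher over the list alone, median 1.00, adjusted p = 5.5e-25, and 0.0991 with an estimated correlation). So were oxidative phosphorylation (1 higher over the list alone, median 0.33, adjusted p = 1.4e-07, and 0.564 with an estimated correlation), antimicrobial (1 higher over the list alone, median 1.26, adjusted p = 1.4e-06, and 0.0967 with an estimated correlation) and stress keratin genes (1 higher over the list alone, median 1.45, adjusted p = 1.2e-06, and 0.564 with an estimated correlation). AP-1 genes were shifted down (0 over the list alone, median -0.56, adjusted p = 9.8e-06, and 0.564 with an estimated correlation). Shifted up too were the unfolded protein response (adjusted p = 0.00177), the IL-17 response (0.0102) and suprabasal genes (0.0102), and down type I interferon (0.0102), hypoxia (0.0304) and clock genes (0.0439), with adjusted p = 0.564, 0.564, 0.684, 0.684, 0.684 and 0.564 with an estimated correlation. Stress, antimicrobial and sterol lists kept their call without any of the 8 libraries. Markers of fibroblasts (-3.55, adjusted p = 1.0e-09), melanocytes (-2.69, 7.6e-05), Langerhans cells (-1.30, 0.00251), the follicle (-0.61, 7.6e-05), the infundibulum (-0.83, 0.0124) and the hair shaft (-0.89, 0.0242) were shifted down at 6 h. They had adjusted p = 0.26, 0.137, 0.544, 0.0732, 0.554 and 0.554 with an estimated correlation.

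The other 8 lists that differed at 6 h each lost their call without some library. The adjusted p reached 0.0746 for oxidative phosphorylation, 0.543 for clock genes, 0.328 for AP-1, 0.417 for type I interferon, 0.525 for the IL-17 response, 0.822 for the unfolded protein response and 0.991 for hypoxia, whose sign turned without 6 h post-imiquimod 1 (0.975). Suprabasal genes turned down without day 30 control 2 (0.0228) and, not called, without day 30 imiquimod 1 (0.767).

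At 12 h no gene's wound response differed by edgeR (0 genes, 503 at an unadjusted p under 0.05, 1 by DESeq2, 0 with the block). Sterol and lipid synthesis genes were again shifted up (3 higher over the list alone, median 0.66, adjusted p = 2.3e-17, and 0.232 with an estimated correlation, 26 of 26 positive). So were oxidative phosphorylation (0 over the list alone, median 0.34, adjusted p = 2.6e-09, and 0.737 with an estimated correlation), antimicrobial (0 over the list alone, median 0.61, adjusted p = 0.00108, and 0.232 with an estimated correlation), stress keratin (0 over the list alone, median 0.79, adjusted p = 0.0043, and 0.841 with an estimated correlation) and unfolded protein genes (0 over the list alone, median 0.18, adjusted p = 0.0157, and 0.853 with an estimated correlation). Clock genes were shifted down (0 over the list alone, median -0.19, adjusted p = 0.0157, and 0.737 with an estimated correlation). The score of the sterol list differed after imiquimod by -0.46 and -0.85 in the pairs of libraries at day 30, by 0.31 and 0.20 at 6 h and by -0.07 and 0.09 at 12 h, where the list was not called for prior imiquimod (adjusted p = 0.653). The migration list, not called, had a positive median but a test direction downward. With the replicate block suprabasal (up, 0.0137), IL-17 (up, 0.0191), AP-1 (down, 0.0466) and hypoxia genes (down, 0.0191) were called as well, each with adjusted p = 0.757 with the block and an estimated correlation. Apart from sterol genes every called list lost its call without some library, with adjusted p up to 0.0904 for antimicrobial and oxidative phosphorylation genes. It reached 0.112 for stress, 0.442 for clock and 0.347 for unfolded protein genes, whose sign turned. Markers of fibroblasts (-2.57, adjusted p = 0.000323), melanocytes (-0.97, 0.0287), the follicle (-0.26, 0.0263) and histones (-1.23, 0.0283) were shifted down, with adjusted p = 0.473 for the follicle and 0.522 for the others with an estimated correlation. The fibroblast score was 0.289 and 0.416 in 12 h control wounds and -0.264 and 0.569 in post-imiquimod wounds, after the single high score at day 30.

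The shared comparison took the mean effect of prior imiquimod over day 30, 6 h and 12 h. Aim2 was higher, at 11.9 ± 3.75 against 1.52 ± 0.524 CPM over 6 libraries each (2.99 ± 0.19, adjusted p = 1.2e-05), and so was Casp1, at 33.5 ± 7.99 against 13.1 ± 3.94 CPM (1.38 ± 0.16, adjusted p = 0.00343). Both kept their call without any of the 12 libraries, with adjusted p values of at most 0.000227 and 0.0175. Casp4 (0.71 ± 0.11) and Casp12 (1.24 ± 0.22), inflammatory caspase genes beside Casp1 on chromosome 9, were higher too. So were Tmprss11g (1.51 ± 0.23), Lgi2 (2.31 ± 0.36), the formin gene Fmnl2 (1.19 ± 0.17), the mitochondrial gene Chchd10 (0.99 ± 0.17) and Ly6e (0.58 ± 0.10). Lower were H2-M2 (-1.65 ± 0.27), the transglutaminase gene Tgm7 (-1.49 ± 0.25), the matrix genes Fn1 (-1.48 ± 0.24), Col6a1 (-1.06 ± 0.17) and Itih5 (-0.91 ± 0.15), the cytokine receptor gene Il2rg (-0.95 ± 0.15) and Creb5 (-0.76 ± 0.13). Of genes outside the rule, chosen after their values were seen, Zfp608 (-2.45 ± 0.18) and Gpc3 (-2.54 ± 0.22) were lower and Vav1 (1.66 ± 0.18) and the granule proteoglycan gene Srgn (2.95 ± 0.40) higher. S100a8 (2.39, adjusted p = 0.000191, against 0.279) and S100a9 (2.21, 0.000233, against 0.377) passed with the replicate block, and Lgi2 (0.11) and Col6a1 (0.0759) did not. In all 35 genes passed by edgeR, 14 higher and 21 lower, 164 by DESeq2 and 105 with the block, which shared 33 of the 35. More were higher than lower without day 30 control 2 (24 and 16), day 30 imiquimod 1 (8 and 4) or 2 (7 and 5), 6 h post-imiquimod 1 (12 and 10) or 12 h post-imiquimod 2 (4 and 3).

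The other 14 named genes of the shared comparison were less secure. All 14 lost their call without 6 h control 1 (adjusted p up to 0.149), post-imiquimod 2 (0.147), 12 h control 1 (0.17) or 2 (0.176) or post-imiquimod 2 (0.184). Leaving out day 30 control 1 ended 3 of the calls (up to 0.0688), day 30 control 2 ended 5 (0.104), day 30 imiquimod 1 ended 10 (0.126) and imiquimod 2 ended 12 (0.116). Without 6 h control 2 it was 9 (0.112), without 6 h post-imiquimod 1 also 9 (0.135) and without 12 h post-imiquimod 1 it was 11 (0.119).

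IL-1 and inflammasome genes were higher as a list in the shared comparison, with 3 of 17 past the test over all genes (4 higher and 1 lower over the list alone, median 0.03, adjusted p = 3.0e-06, and 0.0995 with an estimated correlation). So were antimicrobial genes (3 higher over the list alone, median 0.45, adjusted p = 3.0e-06, and 0.0995 with an estimated correlation), the IL-17 response (1 higher over the list alone, median 0.69, adjusted p = 3.0e-06, and 0.23 with an estimated correlation), stress keratins (1 higher over the list alone, median 0.32, adjusted p = 7.1e-05, and 0.513 with an estimated correlation) and oxidative phosphorylation (1 higher over the list alone, median 0.17, adjusted p = 2.0e-09, and 0.513 with an estimated correlation, 31 of 31 positive). Clock genes were lower (2 lower over the list alone, median -0.34, adjusted p = 3.0e-06, and 0.0995 with an estimated correlation). These 6 kept their call without any of the 12 libraries. Another 8 called lists had medians of -0.21 to 0.08. Each was lost without some library or with an estimated correlation (adjusted p = 0.513 or more). Higher were interferon gamma (adjusted p = 0.00156, up to 0.322 without 1 library), migration (0.0178, up to 0.44) and unfolded protein genes (0.0294, up to 0.991). Lower were AP-1 (0.0111, up to 0.908), cell cycle (0.00034, up to 0.68), glycolysis (0.000246, up to 0.0814), hypoxia (0.000596, up to 0.128) and sterol genes (0.0236, up to 0.622, with the sign turned without day 30 control 2). Hair shaft markers were lower (-0.53, adjusted p = 0.000913, 0.935 with an estimated correlation). The block called 2 cell or RNA lists.

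Libraries with the same replicate number and time formed 6 pairs. The IL-1 and inflammasome score was higher after imiquimod in 6 (mean difference 0.30, SD 0.13) and that of glycolysis in 0 (-0.20, SD 0.10). Each had a two-sided exact sign-flip p of 0.03125, the smallest that 6 pairs can give, and 0.281 after adjustment over 21 lists. Stress keratin (0.54, SD 0.72) and antimicrobial scores (0.61, SD 0.73) were higher in 5 of 6 pairs, with exact p values of 0.156 and 0.125. Oxidative phosphorylation was higher in the 4 pairs of wounds (0.25 to 0.30) and lower in both day 30 pairs (-0.03 and -0.07). Of the 6 lists that kept their call, only IL-1 genes had both day 30 pairs in its direction. Few genes, Aim2 (2.99) among them, carry that score, given the low median above.

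The genes that moved at day 6 were followed as sets of 1831 higher and 1677 lower genes in libraries that share none with day 6. At day 30 their medians were -0.01 and 0.01, while the test pointed up for both (adjusted p = 0.341 and 0.633). At 6 h the higher set had a median of 0.24 with 72.7% of genes positive (adjusted p = 6.4e-18). The lower set had -0.32 with 16.6% positive (2.4e-19, and adjusted p = 0.0557 with an estimated correlation). At 12 h the medians were 0.20 (79.1%, 5.1e-18) and -0.29 (14.1%, 2.6e-27). With an estimated correlation the other 3 had adjusted p = 0.0440. With the replicate block as well it was 0.0991 and 0.0809 at 6 h and 0.0991 and 0.0660 at 12 h. In wounds of control mice the sets had medians of 0.73 and -0.82 at 6 h and 0.91 and -0.86 at 12 h (adjusted p = 0.0557 for all but the higher set at 12 h, 0.0440, with an estimated correlation). Genes higher in 12 h control wounds (1415) had a median of 0.16 in prior imiquimod at 6 h (adjusted p = 2.5e-09, and adjusted p = 0.113 with an estimated correlation) and lower ones (1414) -0.26 (1.1e-10, and 0.0557). Genes higher in 6 h control wounds (1623) had a median of 0.09 at 12 h (0.00037, and adjusted p = 0.340 with an estimated correlation) and lower ones (1703) -0.16 (3.0e-09, and 0.168). At 6 h the medians of fibroblast, melanocyte, follicle and hair shaft markers were -1.80, -1.22, -0.38 and -2.23.

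**Figure D3:**
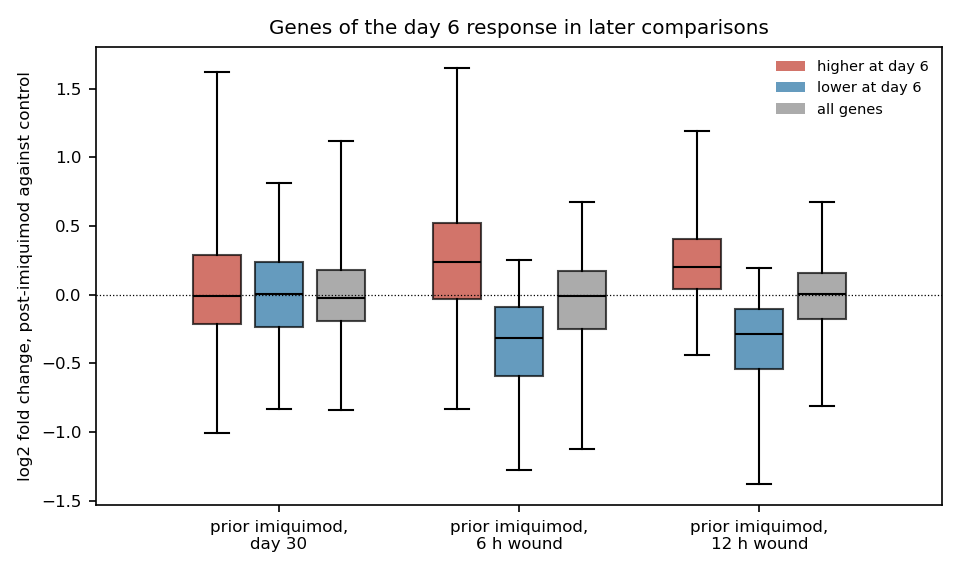
Log2 fold change of prior imiquimod against control at day 30, 6 h and 12 h for the 1831 genes higher at day 6, the 1677 lower and all genes (boxes are quartiles, whiskers the 5th and 95th percentile). The medians of the sets are 0.24 and -0.32 at 6 h and -0.01 and 0.01 at day 30.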

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

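The tests of leukocyte transcripts and of other cells were chosen only after their result was seen, as was the replicate block (libraries of a time point with the same replicate number) for the wound response difference. The depth and gene family tests were written down before their own results were seen, though thinning was added after the data were seen.

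The effect of imiquimod differed between day 6 and day 30, by a test of the difference, for 3894 genes and 14 pathway lists. All 14 list calls were lost with an estimated correlation (lowest adjusted p = 0.189). Genes named at day 6 with a more positive effect there were S100a9 (10.85), S100a8 (10.50), Sprr2d (10.11), Lcn2 (8.31), Slc7a11 (7.77), Chil1 (7.62), Stfa3 (7.49), Cdhr1 (5.27), Krt16 (5.19), Igfbp2 (5.02), Serpinb3a (11.10) and Il1f6 (9.80), as log2 differences. Sprr2b had 13.23, a fitted value against day 6 controls without a read that depends on the prior count and is no bound. Growth and metabolism genes among them were Slc16a1 (4.36), Hk2 (2.84), Slc16a3 (2.86), Stc2 (4.75), Egln3 (3.30), Car12 (1.78), Ccne1 (2.38), Rrm2 (2.24), Mcm5 (1.82), Ndufa4 (2.55), Cycs (1.71) and Uqcrq (1.65). Stress response and sterol genes were Trib3 (3.04), Asns (1.65), Creld2 (1.37), Sqle (3.23) and Mvd (3.37). More negative at day 6 were Dab1 (-4.95), Skint7 (-5.87), Cdh4 (-5.54), Ntrk2 (-5.34), Limch1 (-5.24), Ache (-4.78), Tnxb (-4.94), Cyp2w1 (-4.63), Krt15 (-4.73), Lgr6 (-2.41), Usp18 (-4.64), Mx2 (-3.30), Klf2 (-2.53), Fosb (-2.56), Hlf (-3.98), Npas2 (-3.81) and Nr1d1 (-2.51).

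The wound response differed after imiquimod for 11 pathway lists at 6 h and 6 at 12 h, all lost with an estimated correlation (lowest adjusted p = 0.0967 and 0.232), while no gene passed (0 at either time). Lists of cells or RNA quality differed, 6 lower at 6 h and 4 lower at 12 h (6 called with the block). None did with an estimated correlation (lowest adjusted p = 0.0732 and 0.473). Fibroblast medians were -3.55 and -2.57. With the block the response differed for 3 genes at 6 h, S100a8 (4.42), S100a9 (4.19) and Gk (1.42).

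Aim2 and Casp1, whose effect was not shown to differ between day 6 and day 30, were higher after imiquimod in 6 of 6 pairs of libraries (mean 10.2, SD 4.01, and 20.1, SD 5.35, CPM). Immune cells, for which the sort by integrins, Sca1 and CD34 names no marker of exclusion, were argued against: the sum of the leukocyte transcripts Ptprc, Lyz2, Tyrobp, Fcer1g, Laptm5 and Coro1a changed by -0.0617 CPM (SD 1.09) and reached 3.44 CPM at most in a library, although the list of Langerhans and dendritic cells, which shares Tyrobp and Fcer1g with this sum, was called higher at day 30 (median 0.57) and 12 h (0.55), with adjusted p = 0.595 and 0.740 with an estimated correlation, and although Vav1 (7.68 against 1.98 CPM), Srgn (1.27 against 0.172) and, with the block, H2-Ab1 (10.9 against 4.69), which leukocytes express as well, were higher in the shared comparison. A difference in depth was argued against too, since with libraries thinned to 1 total the higher adjusted p of both genes was 0.00324. Reads shared with the gene family around Aim2 stay open for Aim2, since the summed family changed by 55.3 CPM with an SD of 111, mostly Ifi202b; the reading of this test was changed after its result was seen. A lasting change of the stem cells themselves may account for Casp1, and stays open for Aim2, as a hypothesis that no test here separates from other differences between the treated mice.

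Genes of the day 6 response were shifted the same way in post-imiquimod wounds at 6 h by the test with a preset correlation; with an estimated correlation the adjusted p was 0.0440 for the higher set and 0.0557 for the lower, and with the replicate block as well both calls were lost (0.0991 and 0.0809). A difference in depth was argued against, since the higher set kept a median of 0.23 after thinning. A smaller share of other cells was argued against for the higher set, since it would raise basal epidermis genes at least as much, and the 10 of them outside both sets had a median of -0.0754, below that of the higher set by 0.313 (SD between them 0.154, and 0.212 over all 20). For the lower set a smaller share of other cells cannot be told apart from a change in the cells. The sort for integrin α6, integrin β1 and Sca1 without CD34 is meant to leave out most other cells. Still, 10 genes of the set stand in the lists of such cells. The members outside these lists had a median of -0.32, and such lists name few of the genes those cells express. Earlier inflammation, the difference the design names, stays open for both sets and was not tested apart from other differences between the treated mice.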

How the results depend on the processing

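Leaving out the day 30 libraries numbered 1 (libraries of one sex), thinning to equal depth and the replicate block for lists, sets and wound response differences were chosen only after the data were seen. A count of another strand could not be tried, since the files hold 1 column.

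Of the values that answer a comparison, 224 kept their direction and side of the threshold, or stayed within 1.5 times of a count, 82 moved, 8 weakened and 1 turned. Of the values for named genes and lists 3359 kept both, 622 weakened, 56 strengthened and 22 turned. Where no cause is given, the cause was not tested. With 2 libraries per group few changes of 1 log2 unit can be found (25% in the simulated data), and leaving out 1 library leaves an arm of 1.

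With no low-count filter 151 genes were called at day 30, 441 at 6 h and 182 at 12 h. Wound response differences had 255 and 69 and the shared comparison 532, all kept by the filter. S100a8 at 6 h had adjusted p = 7.1e-87 with 372 ± 326 CPM after imiquimod, so the calls are doubtful. DESeq2 called 20 at day 30, 131 at 6 h, 27 at 12 h, 27 and 1 for the differences and 164 in the shared comparison. With only the compared libraries 0 were called at day 30, 0 at 6 h, 9 at 12 h, 3270 for wounding at 6 h in control mice and 1772 for day 6 against day 30.

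The replicate block within time points called 5 genes at day 30, 28 at 6 h, 20 at 12 h, 3 for the difference at 6 h, 5927 for day 6 against day 30 and 105 in the shared comparison, and lists numbered 4 at day 30 and 10 for the difference at 12 h. A replicate block over all libraries called 1 gene and 3 lists at day 30. Thinned libraries gave 1 gene at day 30 (Aim2), libraries of one sex 1 at day 30 (Gpc3) and 1 for the difference at 6 h (Pnpla1), both named after their values were seen, and RLE scaling 2 lists at day 30.

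With an estimated correlation no list was called (0) at day 6, day 30, 12 h, in the 4 wounding comparisons, in both differences, for day 6 against day 30 and in the shared comparison, and 1 was called at 6 h. Adding the replicate block to the estimated correlation, 1 was called at 6 h and 1 for day 6 against day 30, and 0 elsewhere. Estimated from 8 residual degrees of freedom, this correlation is itself uncertain. Transferred sets weakened with an estimated correlation: adjusted p was 0.0557 for genes lower at day 6 in the 6 h comparison and in both control wounds, for genes higher at day 6 in 6 h control wounds and for genes lower in 12 h control wounds at 6 h. It was 0.113 for genes higher in 12 h control wounds at 6 h, and 0.34 and 0.168 for genes higher and lower in 6 h control wounds at 12 h. With all 3744 genes higher at day 6 and no fold threshold the set's adjusted p at day 30 was 0.0276, with the sign of the median turned.

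Leaving out 1 library gave 4200 to 5589 genes at day 6, 0 to 2 at day 30, 0 to 5 at 6 h and 0 at 12 h. Wounding gave 3252 to 4958 at 6 h and 2846 to 4302 at 12 h in control mice, and 4044 to 5486 and 4202 to 5215 in post-imiquimod mice. The fold of called named genes moved over 1.5 times without some library for 30 of 62 at day 6, 26 of 43 at 6 h and 23 of 42 at 12 h in control wounds. Day 6 against day 30 gave 2229 to 3997 and the shared comparison 7 to 49. Lists called numbered 4 to 10 at day 30, 9 to 12 at 6 h, 7 to 12 for 6 h wounding in post-imiquimod mice and 5 to 11 for the difference at 12 h.

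Lists that turned without 1 library had these adjusted p values. For a list called in the full fit they run over all left-out libraries, and for one not called there they are only those of the 1 or 2 libraries without which it passed in the turned direction. At day 30 they were 0.0207 to 0.0359 for hypoxia, 0.00553 to 0.0122 for oxidative phosphorylation, 0.000137 for suprabasal genes, 0.00101 for heat shock and 0.00483 for the unfolded protein response. Cell cycle genes had 1.0e-14 to 0.0538 at 6 h (turned at 0.000507) and 1.2e-13 to 0.827 at 12 h, and type I interferon genes 0.000299 to 0.000506 at 12 h. For the difference at 6 h they were 3.6e-13 to 0.767 for suprabasal genes, 1.3e-06 to 0.991 for hypoxia, 0.0256 for heat shock and 0.00184 for the cell cycle. For that at 12 h they were 0.000315 for suprabasal genes, 0.0467 for glycolysis, 2.0e-10 to 0.347 for the unfolded protein response and 0.0363 for heat shock. In the shared comparison they were 0.000543 for suprabasal and 3.1e-07 to 0.622 for sterol genes.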

Other observations

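The tests of Xist and Y-linked reads, of neighbouring genes and of the clock were chosen only after their result was seen, and the overlaps of called genes are given as counts without a test. The split tests were chosen before.

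Imiquimod at day 6 and wounding of control skin moved many of the same genes. Of the 3744 genes higher at day 6, 1552 were also higher at 6 h of wounding (675 if the calls were independent) and 254 were lower. At 12 h of wounding 1709 were higher (616 if independent) and 129 lower. Among the 2589 genes lower at day 6, 1059 were lower at 6 h (432 if independent) and 1091 at 12 h (371).

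The 35 genes that passed in the shared comparison had mostly moved the same way at day 6. All 14 higher ones were higher at day 6 (3.03 if the calls were independent), 17 of the 21 lower ones were lower (3.14 if independent), and none had moved the opposite way (0). Zfp608 was lower (-3.22, adjusted p = 1.7e-05), as was Gpc3 (-3.11, adjusted p = 6.9e-05). Vav1 (4.43, adjusted p = 4.3e-06) and Tmprss11g (2.81, adjusted p = 0.000185) were higher.

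Both day 30 libraries numbered 1 lacked Xist and held Y-linked reads, although the samples are labelled female. Their highest Xist level was 0.00523% of the median of the others and their Y-linked level at least 3525 times the highest of the others, which is consistent with libraries made from male mice. A mixture of cells from both sexes was argued against, since with 3 counts added the level was 0.0209%. Each day 30 group holds 1 such library, so sex and replicate number coincide at day 30, and the day 30 groups that serve as the baseline of the wounding comparisons share this.

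For the 35 genes that passed on the mean effect over day 30, 6 h and 12 h (2, 6 and 0 passed at the single times), chance could not be excluded: 17 of 100 splits of the 12 libraries within time points (of 108 possible) gave at least as many, and the highest other gave 475. Among the 30 splits that part every pair of libraries with 1 replicate number the real one alone did, and the highest other gave 1. Of the 70 that keep a pair together 16 did, which points to a structure of the samples along the replicate number. With the replicate block fitted, 1 of 32 splits that part every pair, the real one, gave 105 genes or more, and the highest other gave 35. A share of 1 in 32 is the smallest that these splits can give. Chance was thus argued against in the fit with the block, though not excluded.

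The genes called in the shared comparison included neighbours on the chromosome. Of 34 called genes with coordinates, 3 pairs lay within 100 kb, all among Casp1, Casp4 and Casp12 on chromosome 9, against a mean of 0.163 pairs in 10000 random sets (as many in a share of 0.0012). Among the calls with the replicate block, 102 genes held 9 pairs against 1.52 (share 2e-04). As a hypothesis, the caspase genes may be regulated together, which rests on 1 locus without the block and was tested on the data that showed it.

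Clock genes lower at day 6 may reflect another time of collection. Npas2 and Nr1d1 fell (adjusted p at most 0.00101), as did Arntl (-0.63, 0.00386) and Per3 (-1.24, 0.00678). Cry1 (-0.06) and Clock (0.19) did not. A shift in time stays open, since daily peaks were not measured. Times of collection are not given in the sources used here.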
